A study of Mus musculus with 7 samples.

How the data were processed

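Gene expression was measured in bladders of male FVB/N mice that carry enhanced green fluorescent protein (EGFP) under the promoter of Actg2, which encodes smooth muscle gamma-actin. Each sample was hybridized to a 1-colour Affymetrix mouse 430 2.0 array after 2 rounds of amplification of total RNA. The 7 arrays were 3 adult bladders (Theiler stage 28), 3 bladders of postnatal day 1 (Theiler stage 27) and 1 reference made from whole wild-type newborns, a pool of 4 males and 4 females. The title of the reference names bladders, whereas its source and protocol describe whole animals, and it was read as whole animals here. As far as the labels tell, each bladder array is 1 animal's or 1 sample's RNA, so p-values measure the spread between single samples. Adult tissue was stored in liquid nitrogen and newborn tissue in a freezer, so stage and storage cannot be told apart.

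The deposited values are intensities on a linear scale, without detection calls. GCOS, the scanner maker's software, is named in the submitters' processing notes, with its version not given. The summary method and the scaling target are not given in the sources used here. From the values, the mean without the highest and lowest 2% was 1500.01 on every array, so the authors scaled each array to a common mean. The table holds 45101 probe sets, of which 64 Affymetrix controls were left out. Of the other 45037, 34945 name 1 gene in the platform annotation, 932 name several and 9160 name none.

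Values were analysed as log2(intensity + 49), where 49 is the 20th percentile of all values of the series, rounded. The rule fixed before the data were examined was to centre the arrays if their medians differed by over 0.5 log2. On that scale the medians of the 6 bladder arrays spanned 0.485, and the arrays were not centred. For the bladder arrays this reading lies close to the limit: without the added 49 the span was 0.578, which would have led to centring. Over all 7 arrays, which the comparison with the reference used, the span was 0.906. That is well over the limit and would have led to centring, but the main values of that comparison were not centred either. Results with median centring are therefore given for the counts and where they end or make a list's call. For adult against postnatal day 1 bladder, probe sets above their array's median in at least 3 of the 6 arrays were tested. For postnatal day 1 bladder against the reference, 1 of the 4 arrays compared was enough.

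Tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend, both directions, Benjamini-Hochberg adjusted p under 0.05). The fit for the stages held the 6 bladder arrays. The fit for the reference held all 7 arrays in 3 groups, so that its spread came from the bladder arrays, and the single reference array was assumed to vary like them. One probe set stood for each gene, the one with the highest mean among those naming 1 gene. Before the data were examined, 47 gene lists (922 genes on the array) and the rule for naming genes were fixed. Lists with at least 5 tested genes were compared with all other genes by limma's camera with a preset correlation of 0.01, adjusted over the lists. An estimated correlation within each list and fry, another limma test, were alternatives. Fry tests a list against no change and not against the other genes, so its counts answer another question. Members were also adjusted over the list alone. Named genes were the 10 largest rises and 10 largest falls among called genes whose groups did not overlap, Actg2 and Acta2, up to 4 members of each list by adjusted p, members that state an exception, and sex-linked genes as a check of the labels. Probe sets without a gene, with several genes, or with clone names were counted and not named.

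Results were recomputed with pseudocounts of 9 and 165, quantile normalization, median centring, no filter, a filter at the 70th percentile, eBayes without a trend or robust, array weights, all 7 arrays in 1 fit, genes by the mean of their probe sets, a 2-fold minimum, and leaving out each bladder array, choices fixed before the data were examined. After the control probe sets were seen, 2 alternatives were added: the spike-in level as a covariate, and leaving out the adult and the newborn array with the highest spike-in signal. All 10 splits of the 6 bladder arrays into 3 and 3 were also run.

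The stage comparison was tested on simulated data of 3 against 3 arrays. Of planted changes of 1, 2 and 3 log2 units, 6.06%, 62.7% and 88.1% were called, and 6 of 23104 unchanged probe sets were called. Against a single reference array the shares were 1.52%, 10.4% and 40.3%, with 1 of 28116 unchanged probe sets called. In both, camera called 5 of 5 shifted lists and 0 of 35 unshifted ones. With an estimated correlation it called 5 of 5 in the stage design and 0 of 5 in the reference design. The simulated noise was independent between probe sets and the lists were drawn at random. These list counts therefore do not cover lists with correlated members, such as mitosis (estimated correlation 0.32) or ribosomal proteins (0.55) between the stages. For probe sets, 200 changes were planted in each comparison, whereas 1829 and 2101 probe sets were called in the data. The adjustment is stricter when few probe sets change, so the simulated shares may understate those in the data. The number of arrays limits the precision of every value below.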

Results

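Male bladders were profiled at 2 ages, with 3 adult and 3 postnatal day 1 bladders on 1 array each, next to 1 array of whole newborn mice. Median intensities were 226, 312 and 234 in adult replicates 1 to 3, 263, 209 and 290 in postnatal day 1 replicates 1 to 3, and 434 in the reference. Between replicates of a stage, log2 intensities correlated across probe sets with r from 0.896 to 0.926, except adult replicates 1 and 3, at 0.970. These 2 arrays also lay closest in the SD of their log2 difference, 0.483. The ratio of the 3' to the 5' probe set, a sign of RNA quality, was higher in adult bladders for Actb (3.84 to 5.15, newborn 1.85 to 3.70) but not for Gapdh (15.3 to 19.6, newborn 19.1 to 30.9). The hybridization spike-ins were 2.35 times the lowest array's level in adult replicate 2 and 1.68 times in postnatal day 1 replicate 3. Adult replicates 1 and 3 also carried transcripts of male accessory glands: the mean log2 value of 13 such markers was 9.74 and 9.65 there, 7.26 in adult replicate 2 and 7.21 to 7.46 in newborn bladders. Xist, the transcript that silences an X chromosome in females, gave 2.54 to 110 on its main probe set in the bladders and 51279 in the reference. Eif2s3y, a Y-linked gene, gave 3394 to 8998 in the bladders and 2039 in the reference, a pool of both sexes.

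The comparison of adult with postnatal day 1 bladder asked how the growing organ differs from the mature one. Cell division genes were far lower in adult bladder: Top2a, the topoisomerase that untangles chromosomes, fell by 3.88 on the log2 scale, from 9249 ± 3240 to 559 ± 31.1 (SD, n = 3). Lists of imprinted and fetal growth genes, collagen and basement membrane assembly, neurons and striated muscle also shifted down, with shares from 5 of 22 neuron markers to 7 of 13 skeletal muscle markers passing the test, and each of these calls, cell division included, was lost with an estimated correlation (adjusted p from 0.0945 to 0.375). Lists of antigen presentation, interferon response, complement, xenobiotic metabolism and the circadian clock shifted up, with shares from 4 of 17 clock genes to 4 of 6 MHC class II genes passing, and these calls were lost as well (adjusted p from 0.0945 to 0.556 with an estimated correlation). The contractile genes of smooth muscle and the genes of urothelial differentiation did not shift as groups. Actg2 itself read 62260 ± 28900 in adult and 73670 ± 9510 in newborn bladder (SD, n = 3; log2 difference -0.33, adjusted p = 0.536), at 60.5% to 84.5% of the highest value of each array. Without adult replicate 2 the Actg2 difference was -0.68, with adjusted p = 0.0213, and it was -0.62 with array weights (0.0408) and -0.61 without the 2 arrays of highest spike-in signal (0.0369).

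In all, 1829 of 23304 probe sets changed, 869 higher and 960 lower in adult bladder. By gene, 1058 of 11958 changed, 476 higher and 582 lower. Of the 39 lists tested, 19 shifted, 7 up and 12 down. With an estimated correlation, which rests on 4 residual degrees of freedom, camera called 0 of the 39, with 9 at an unadjusted p under 0.05, and fry called 15. The 9 splits that mix the stages gave 0 changed probe sets each, but 8 to 16 lists by camera with the preset correlation. Each such split keeps part of the stage difference and adds the rest to the spread, so neither count is a rate of false calls. A list call at that setting is weak evidence without its members, since 0 of the 39 held with an estimated correlation. Leaving out single arrays moved the probe set count to 689 (adult replicate 1), 598 (adult replicate 3), 872, 717 and 1150 (postnatal day 1 replicates 1, 2 and 3), and to 2219 without adult replicate 2. Higher calls then numbered 182 to 952 and lower calls 320 to 1267. The filter still asked for 3 arrays, so probe sets above the median only in the stage left with 2 arrays were no longer tested. With median centring 1344 probe sets (616 higher, 728 lower) and 744 genes changed. Without the 2 arrays of highest spike-in signal 1873 probe sets changed, 1095 of them among the 1829 and in the same direction.

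The largest falls were in Fbn2, a fibrillin of fetal microfibrils (-6.84, from 26410 ± 2340 to 197 ± 97.1), in the developmental muscle myosins Myh8 (-6.01) and Myh3 (-5.91), and in Tnnc2 (-5.66), the troponin C of fast muscle. They continued with Dscc1 (-5.28), a sister chromatid cohesion factor, Krt14 (-5.13), a basal keratin, and Uhrf1 (-5.04), which maintains DNA methylation. Agtr2, the angiotensin receptor typical of fetal tissues, fell by 4.88, Kif2c, a mitotic kinesin, by 4.84, and Dtl, a replication control factor, by 4.81. The largest rises were in H2-Aa (4.84), a chain of MHC class II, Inmt (4.69), a methyltransferase, Pcolce2 (4.67), an enhancer of procollagen processing, and Acaa1b (4.65), a peroxisomal thiolase. Next came Cyp4f15 (4.57), a cytochrome P450, Aldh3a1 (4.39), an aldehyde dehydrogenase, H2-Ab1 (4.21), the other chain of MHC class II, Fam184b (4.08), Fgl2 (3.98), a fibrinogen-like protein, and Gpm6a (3.66), a membrane glycoprotein. Adjusted p for these 20 genes ranged from 7.05e-05 (Fbn2, Tnnc2) to 0.0126 (Myh3), and each kept its call under every alternative in which it was tested. In the adult arrays Myh8, Myh3, Tnnc2, Dscc1, Kif2c and Dtl lay at or below the array median, as did H2-Aa, Pcolce2, Aldh3a1 and H2-Ab1 in the newborn arrays, so the size of these changes depends on the pseudocount. The former genes failed the filter whenever a newborn array was left out, and the latter whenever an adult array was. Their calls were not tested in those settings. The probe sets of H2-Aa, H2-Ab1, Gpm6a, Krt14 and Kif2c can match several transcripts.

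**Figure D1:**
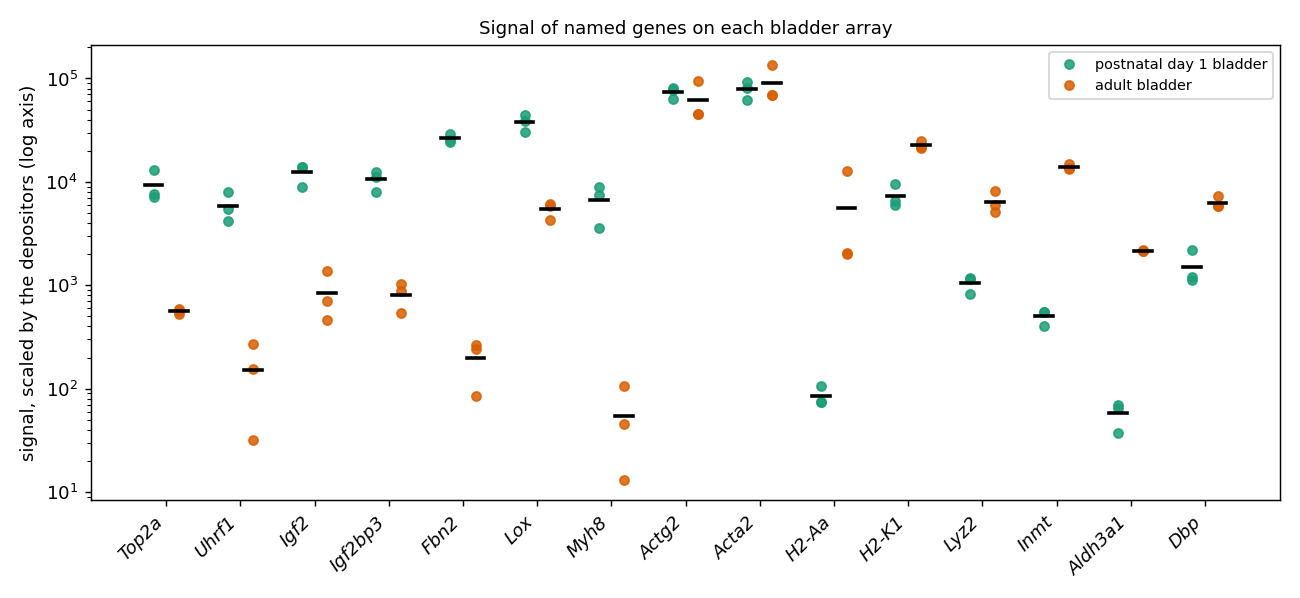
Intensity (log axis, scaled by the depositors) of 15 named genes on each of the 3 postnatal day 1 (green) and 3 adult (orange) bladder arrays, with a black line at each group mean. Top2a read 9249 in newborn and 559 in adult bladder on average, H2-K1 read 7329 and 22720, and the Actg2 groups overlapped.

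Of 37 mitosis genes, 36 fell and 0 rose (37 fell when adjusted over the list alone), with a median of -3.46. Examples beyond Top2a were Cenpa (-3.62), the centromeric histone, Racgap1 (-3.58), a regulator of cytokinesis, and Nusap1 (-3.53), a spindle protein. The list shifted with adjusted p = 1.09e-39, and with adjusted p = 0.0945 with an estimated correlation. Of 33 DNA replication genes, 21 fell and 0 rose (27 fell when adjusted over the list alone), with a median of -1.44. Rrm2, which makes deoxynucleotides, fell by 3.39, Cdt1, a licensing factor, by 2.26, and Tk1, a thymidine kinase, changed by -4.45. The adjusted p was 9.39e-19, and adjusted p = 0.117 with an estimated correlation.

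Of 17 imprinted growth genes, 9 fell and 1 rose (14 and 1 when adjusted over the list alone), with a median of -1.60. Igf2, the fetal growth factor, fell from 12340 ± 2880 to 848.5 ± 473 (SD, n = 3), and Cdkn1c, a brake on the cell cycle, fell by 3.80. Slc38a4, an amino acid transporter, fell by 3.73 and Grb10, an inhibitor of insulin and growth factor signalling, by 1.88. The list's adjusted p was 1.89e-09, and adjusted p = 0.108 with an estimated correlation. The member that rose, Impact, a translation regulator (1.13, adjusted p = 0.0363), lost its call without any single array other than adult replicate 2 (adjusted p from 0.0607 to 0.149), with median centring (0.114), without a filter (0.0575), without a trend (0.0638) and by the mean of its probe sets (0.235). Of 13 fetal RNA-binding and growth regulators, 6 fell and 0 rose (9 fell when adjusted over the list alone), with a median of -1.01. Igf2bp3, a fetal RNA-binding protein, fell by 3.64 and Mycn, a Myc family factor, by 2.34. Their list had adjusted p = 3.46e-06, and adjusted p = 0.0945 with an estimated correlation. Its median was -0.67 without postnatal day 1 replicate 3, where Mycn no longer passed the filter.

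Matrix genes fell in 3 lists. Of 28 genes of fibrillar collagens and their assembly, 7 fell and 0 rose (11 fell when adjusted over the list alone), with a median of -0.78 and adjusted p = 1.11e-06 (adjusted p = 0.375 with an estimated correlation). Lox, which cross-links collagen and elastin, fell from 37940 ± 6770 to 5415 ± 961 (SD, n = 3), Col5a1 fell by 2.02 and Col1a1 by 1.98. The collagen list stood 0.69 higher in adult replicate 2 than in the other adult arrays by its median. Of 17 basement membrane genes, 5 fell and 0 rose (7 fell when adjusted over the list alone), with a median of -0.66 and adjusted p = 0.00207 (adjusted p = 0.375 with an estimated correlation). Lamb1, a laminin chain, fell by 1.30 and Nid2, a nidogen, by 2.09. Of 14 elastic fibre genes, 3 fell and 0 rose (4 and 1 when adjusted over the list alone): Fbn2, Eln, which encodes elastin (-2.11), and Mfap5, a microfibril protein (-1.87). That list's median was -0.38, with adjusted p = 0.0352 and adjusted p = 0.468 with an estimated correlation. Its call was lost with quantile normalization (adjusted p = 0.063), without adult replicate 3 (0.0688) and without postnatal day 1 replicate 1 (0.108), and its median was -0.59 without adult replicate 2 and -0.21 without postnatal day 1 replicate 3.

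Markers of striated muscle were among the strongest falls. Of 13 skeletal muscle markers, 7 fell and 0 rose (8 fell when adjusted over the list alone), with a median of -2.31, adjusted p = 8.54e-09, and adjusted p = 0.0945 with an estimated correlation. Besides the 3 named above, Tnnt3 and Tnnt1, the fast and slow troponin T, fell by 4.50 and 3.97. The skeletal median was -1.33 without postnatal day 1 replicate 1, -1.50 without replicate 2, -1.32 without the 2 arrays of highest spike-in signal, -1.33 without a filter and -3.97 with the filter at the 70th percentile. The filter still asked for 3 arrays when a newborn array was left out. Members at or below the median in all adult arrays, such as Myh8, Myh3, Tnnc2 and Tnnt3, then went untested, so those medians cover fewer members. Of 7 cardiac muscle markers, 3 fell and 0 rose (5 fell when adjusted over the list alone), with a median of -1.90, adjusted p = 0.000467, and adjusted p = 0.117 with an estimated correlation. The cardiac median was -0.93 without a filter and -1.13 without the 2 spike-in-rich arrays. Those 3 were Myl4 (-4.67), a fetal myosin light chain, Actc1 (-1.90), cardiac actin, and Myh7 (-3.76), slow myosin. In newborn bladder Myl4 stood at 195% of its level in whole newborns and Myh8 at 8.23%, and Myh3 ranged from 0.859% to 29% between the 3 arrays.

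**Figure D2:**
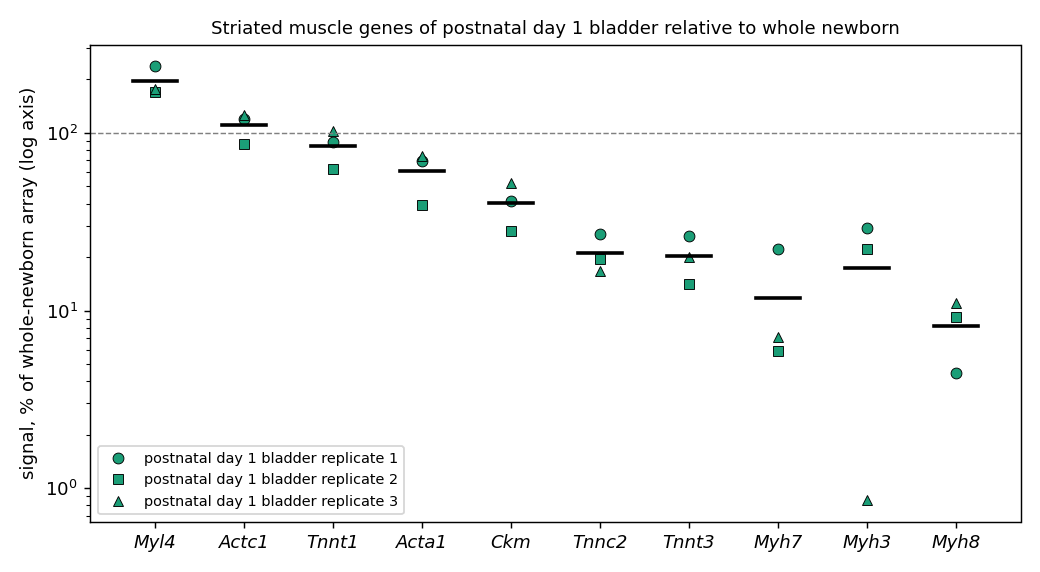
Intensity of 10 striated muscle genes lower in adult bladder, on each postnatal day 1 bladder array, as a percentage of the whole-newborn array (log axis, dashed line at equality), with a black line at each mean. The means run from 195% for Myl4 to 8.23% for Myh8.

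Of 22 peripheral neuron markers, 5 fell and 0 rose (10 fell when adjusted over the list alone), with a median of -1.45, adjusted p = 4.47e-06, and adjusted p = 0.375 with an estimated correlation. Phox2a, a transcription factor of autonomic neurons, fell by 2.31 (adjusted p = 0.0122, or 0.0516 without adult replicate 1). Adult replicate 2 stood apart: the mean log2 value of the list was 10.09, 8.14 and 10.05 in adult replicates 1 to 3, against 10.81, 11.29 and 10.51 in newborn bladders, and here too adult replicates 1 and 3 were the arrays with accessory gland transcripts. The list median was -0.88 without that array, -0.91 without the 2 spike-in-rich arrays and -0.93 with array weights, all still called. Of 15 brain markers, 4 fell and 1 rose (5 and 1 when adjusted over the list alone), with a median of -0.85, adjusted p = 0.00304, and adjusted p = 0.375 with an estimated correlation. Dcx, a microtubule protein of young neurons, fell by 4.77, whereas Gpm6a, which is also a mesothelial marker, rose. Gap43 (-2.83) and Elavl3 (-2.34), among the falls, are also on the peripheral neuron list, and Stmn2, Snap25 and Syt1 were defined on both. The brain list is therefore not separate evidence from the neuron list. The brain list lost its call without postnatal day 1 replicate 1 (adjusted p = 0.11), 2 (0.227) or 3 (0.0758), with the filter at the 70th percentile (0.0798) and without the 2 spike-in-rich arrays (0.227, median -0.46). Without a newborn array Dcx, at or below the median in every adult array, was no longer tested. Brain markers stood lower in adult replicate 2 than in the other adult arrays (median -0.60). The list's median was -1.63 without adult replicate 3 and -0.43 with array weights. Of 37 oxidative phosphorylation genes, 3 fell and 1 rose (the same counts when adjusted over the list alone), with a median of -0.23, adjusted p = 0.0347, and adjusted p = 0.375 with an estimated correlation. That call was lost without adult replicate 1 (0.22), adult replicate 3 (0.112) or postnatal day 1 replicate 3 (0.0684), and without a trend (0.0813). The member that rose was Sdha, a subunit of complex II (1.01, adjusted p = 0.0124), which lost its call without adult replicate 1 (0.0629), adult replicate 3 (0.0795) or postnatal day 1 replicate 2 (0.0604), and without a trend (0.0532).

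Of the immune lists, 4 shifted up, each without a call with an estimated correlation. Of 21 genes of MHC class I and interferon response, 9 rose and 0 fell (14 rose when adjusted over the list alone), with a median of 1.40, adjusted p = 8.64e-09, and adjusted p = 0.0945 with an estimated correlation. H2-K1, a class I heavy chain, rose from 7329 ± 1870 to 22720 ± 2050 (SD, n = 3). B2m, the partner of H2-K1, rose by 1.48, H2-D1 by 2.21 and Nlrc5, the class I transactivator, by 3.25. The probe sets of H2-K1 and H2-D1 can match several transcripts, so their rises may not be specific to each gene. Of 6 MHC class II genes, 4 rose and 0 fell (4 when adjusted over the list alone), with a median of 1.76, adjusted p = 0.000782, and adjusted p = 0.375 with an estimated correlation. H2-Aa read 5577 ± 6140 in adult and 84.97 ± 18.1 in newborn bladder, with 1993.2, 12670 and 2068.5 in adult replicates 1 to 3, and the list's mean log2 value was 9.08, 10.28 and 9.13 there. The list had too few genes to be tested without any 1 adult array or without the 2 spike-in-rich arrays. Of the other 2 genes that rose, Ctss, a protease of antigen processing (1.49, adjusted p = 0.0385), lost its call in 9 of 18 alternatives (adjusted p from 0.0684 to 0.126), and Cd74, the invariant chain (1.95, adjusted p = 0.0202), in 4 (0.0559 to 0.0604). Of 10 complement genes, 5 rose and 0 fell (6 rose when adjusted over the list alone), with a median of 1.05, adjusted p = 0.00378, and adjusted p = 0.299 with an estimated correlation. Serping1, the inhibitor of C1, rose by 1.41, and the list read adjusted p = 0.0504 without the 2 arrays of highest spike-in signal. Of 18 macrophage markers, 2 rose and 0 fell (5 and 1 when adjusted over the list alone), with a median of 0.45, adjusted p = 0.0117, and adjusted p = 0.582 with an estimated correlation. Lyz2, lysozyme, rose by 2.55, and the macrophage call was lost without adult replicate 2 (0.108), postnatal day 1 replicate 2 (0.067) or both spike-in-rich arrays (0.2), with the filter at the 70th percentile (0.0674) and with array weights (0.132). The macrophage median then ranged from 0.18 to 0.32, and was 0.73 without adult replicate 3. Macrophage markers stood 0.55 higher in adult replicate 2 than in the other adult arrays by their median.

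Of 25 xenobiotic metabolism genes, 7 rose and 0 fell (14 rose when adjusted over the list alone), with a median of 0.82, adjusted p = 1.27e-06, and adjusted p = 0.0945 with an estimated correlation. Besides Aldh3a1, Gstm1, a glutathione transferase, rose by 1.97 and Fmo5, a monooxygenase, by 1.44. Of 9 adipocyte markers, 4 rose and 1 fell (the same when adjusted over the list alone), with a median of 0.81, adjusted p = 0.00794, and adjusted p = 0.186 with an estimated correlation. Car3, a carbonic anhydrase, rose by 1.71 and Adipoq, which encodes adiponectin, by 3.65. Fabp4, a fatty acid carrier, fell by 0.74 (adjusted p = 0.0345), a call lost without any single array other than adult replicate 2 (0.067 to 0.143), with median centring (0.108), without a filter (0.083), without a trend (0.127) and by the mean of its probe sets (0.206). Of 17 circadian clock genes, 4 rose and 0 fell (4 when adjusted over the list alone), with a median of 0.67, adjusted p = 0.00794, and adjusted p = 0.556 with an estimated correlation. Dbp, a clock output factor, rose from 1505 ± 595 to 6282 ± 863 (SD, n = 3). Both lists were lower in adult replicate 2 than in the other adult arrays: the mean log2 value was 10.69, 9.67 and 10.70 in adult replicates 1 to 3 against 9.30 to 9.55 in newborn bladders for adipocyte markers, and 10.69, 10.13 and 10.63 against 9.71 to 10.17 for clock genes. The male accessory gland markers ran the same way over the adult arrays (9.74, 7.26 and 9.65), so the rise of both lists went along with transcripts of another tissue in adult replicates 1 and 3. For clock genes adult replicate 2 lay within the newborn range. The adipocyte call was lost without adult replicate 1 (0.0636) or 3 (0.0765, median 0.49) and with the filter at the 70th percentile (0.0642); its median was 0.47 without postnatal day 1 replicate 2 and 1.28 with array weights. The circadian call was lost without adult replicate 1 (0.15, median 0.44) or 3 (0.106, median 0.33). Without an adult array Adipoq and the clock gene Nr1d1, at or below the median in every newborn array, were no longer tested.

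The lists that mark the organ itself were not called. Of 30 contractile genes of smooth muscle, 1 rose, 0 fell and 29 did not pass the test (the same when adjusted over the list alone), with a median of -0.02 and adjusted p = 0.734. On all 6 arrays 6 of the 30 read over 50% of the array's highest value, where the range of the scanner can compress differences. The gene that rose, Ldb3, an adaptor of contractile filaments (2.15, adjusted p = 0.0183), lost its call without adult replicate 1 (0.074), adult replicate 3 (0.0656) or postnatal day 1 replicate 2 (0.0672). Acta2, smooth muscle alpha-actin, was among them, at 77.1% to 96.6%, so that its difference of 0.15 (adjusted p = 0.787), with a negative sign on 1 of its other probe sets, leaves its change open. Of 26 urothelial differentiation genes, 0 passed the limma test, also when adjusted over the list alone, and 7 had an unadjusted p under 0.05 (adjusted p = 0.734 for the list). Their median was 0.01, whereas their mean (-0.04) and the direction of the test were negative. Among 14 basal urothelium genes 1 rose and 2 fell, Krt14 among the latter (adjusted p = 0.211 for the list, but 0.0302, as lower, with fry). Among 17 detrusor receptors and ion channels 3 rose and 0 fell (adjusted p = 0.106, but 0.0211 without adult replicate 2, 0.0473 without postnatal day 1 replicate 1, 0.0475 without the 2 spike-in-rich arrays and 0.029 with array weights).

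Signalling and regulatory lists did not shift between the stages either. None of 15 Hedgehog pathway genes changed (limma, 3 at an unadjusted p under 0.05; median -0.29, adjusted p = 0.379). Of 29 Wnt pathway genes 1 rose and 2 fell (median -0.24, adjusted p = 0.225), among them Rspo2, which enhances Wnt signalling (-2.97). Of 25 BMP and TGF-beta pathway genes 2 rose and 1 fell (adjusted p = 0.962), with a median of -0.07 and a mean of 0.01, and the list stood 0.50 higher in adult replicate 2 than in the other adult arrays. Of 10 retinoid pathway genes 2 rose (4 rose and 1 fell when adjusted over the list alone; median 0.11, adjusted p = 0.485), among them Aldh1a1, which makes retinoic acid (1.52). Of 8 small leucine-rich proteoglycans Prelp rose (2.95) and Aspn, asporin, fell (-2.11; list median -0.22, adjusted p = 0.76). Of 19 posterior Hox genes and mesenchyme regulators 2 rose (median 0.12, adjusted p = 0.283). Of 16 glucocorticoid-responsive genes 1 fell (2 when adjusted over the list alone; median -0.26, adjusted p = 0.225, but 0.00529 without postnatal day 1 replicate 3 and 0.00274 without the 2 spike-in-rich arrays). The immediate early and ribosomal lists stood 1.76 and 0.65 higher in adult replicate 2 than in the other adult arrays by their medians. Of 24 immediate early genes 1 fell (median -0.11, adjusted p = 0.647), but without adult replicate 2 the median was -0.74 with adjusted p = 0.00077, and the list was also called lower with array weights (0.00631) and without the 2 spike-in-rich arrays (2.12e-05). None of 33 ribosomal protein genes, 11 of them over 50% of the highest value on all 6 arrays, passed (limma, 5 at an unadjusted p under 0.05; median -0.13, adjusted p = 0.065); the list was called, as lower, with quantile normalization (adjusted p = 0.0183) and median centring (0.0291), and without adult replicate 2 (1.69e-06), postnatal day 1 replicate 2 (0.00585) or the 2 spike-in-rich arrays (3.6e-06), with array weights (0.000317) and with the spike-in covariate (0.0178).

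Among other cell types, none of 17 endothelial markers (limma, 2 at an unadjusted p under 0.05; median 0.10, adjusted p = 0.739) and none of 8 Schwann cell markers (3 at an unadjusted p under 0.05; median -0.18, adjusted p = 0.805) changed. Of 6 mesothelial markers 2 rose (median 0.20, adjusted p = 0.28, or 0.0469 without a filter). Of 5 mast cell markers Kit, a receptor also found on interstitial cells, rose (1.94), and Hdc, which makes histamine, fell (-3.74, or -2.41 with a pseudocount of 165; list median -0.11, adjusted p = 0.763). Of 22 fatty acid oxidation genes 1 rose (median 0.10, adjusted p = 0.303). Of 6 skin markers 1 fell (median -0.16, adjusted p = 0.308). None of 6 cartilage and bone markers changed (limma, 3 at an unadjusted p under 0.05, and 2 higher and 1 lower when adjusted over the list alone; median 0.50, adjusted p = 0.706).

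**Figure D3:**
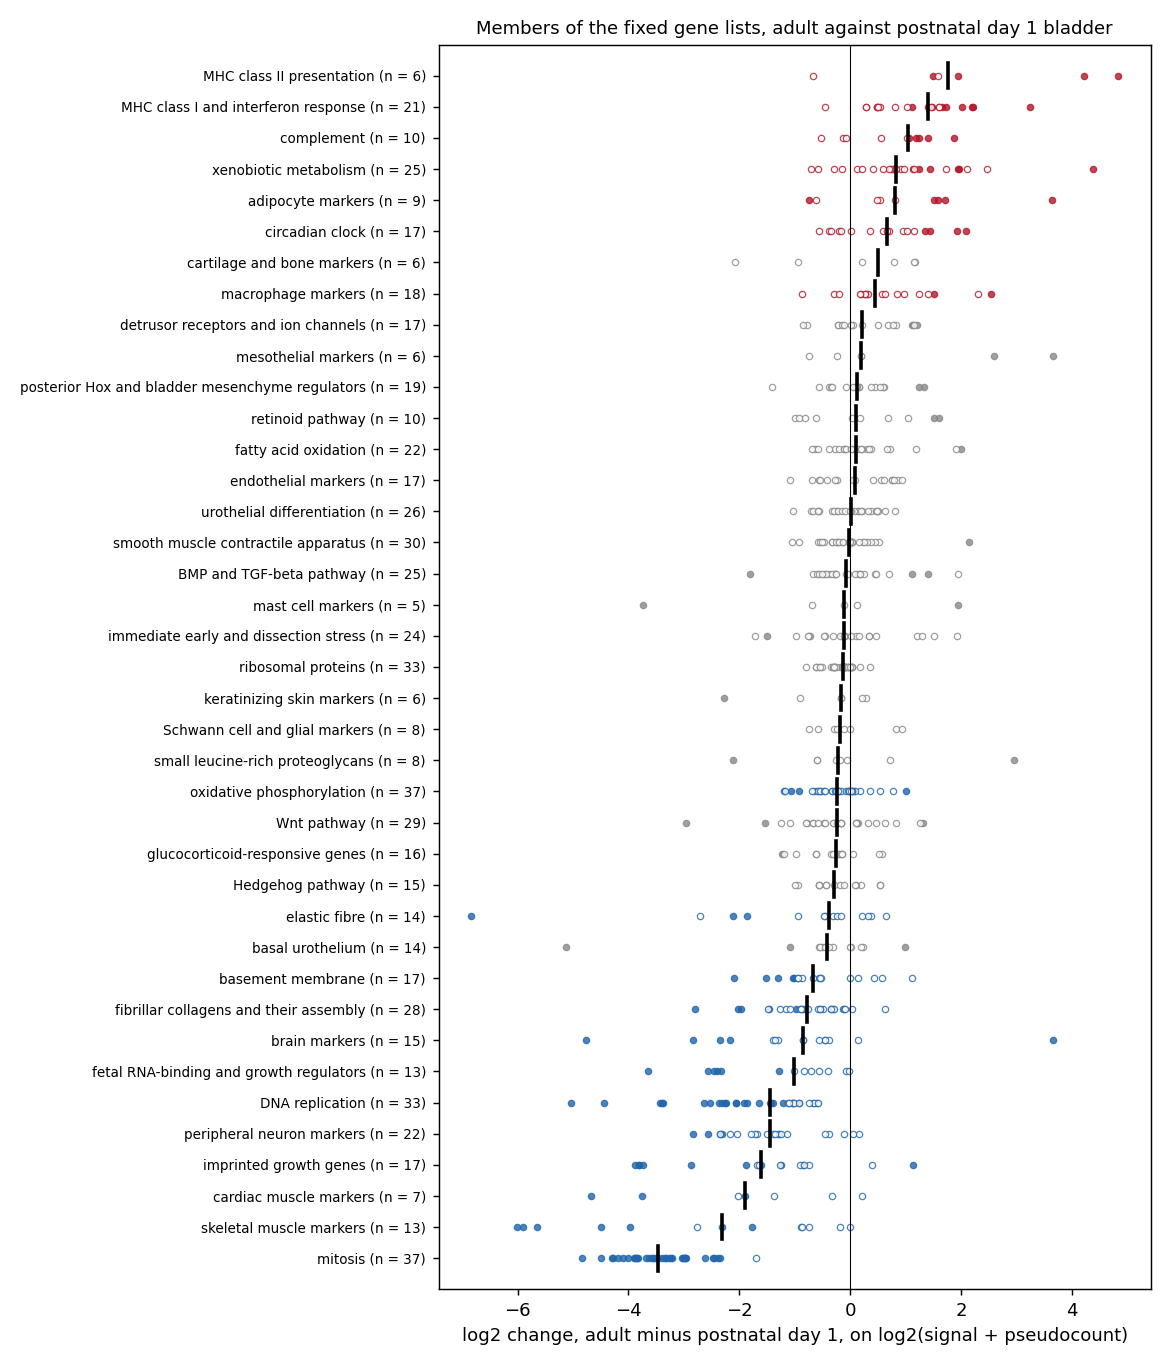
Log2 change, adult minus postnatal day 1 bladder, of each tested member of the 39 lists (1 point per gene, filled if called), with a black line at each list's median. Lists called higher are red, lists called lower blue and the others grey, and medians run from -3.46 for mitosis to 1.76 for MHC class II presentation.

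Postnatal day 1 bladder was compared with whole newborns to ask which genes set the newborn organ apart from the rest of the body. Smooth muscle (23 of 30) and urothelial (15 of 26) genes were higher in bladder, although these list calls were lost with an estimated correlation (adjusted p = 0.0654 and adjusted p = 0.099). Myh11, smooth muscle myosin, read 55480 ± 6780 (SD, n = 3) in bladder against 2324 in the reference, and Upk1b, a uroplakin of the bladder lining, read 58330 ± 5190 against 889. Sonic hedgehog (Shh), a signal from epithelium to mesenchyme, and 7 of 21 posterior Hox genes and mesenchyme regulators were also higher. Markers of pancreas, skeleton, skeletal muscle, intestine and fat were lower, as were those of liver and skin, whose calls were lost with an estimated correlation (adjusted p = 0.0654 and adjusted p = 0.0546). Actg2 read 73670 ± 9510 against 13220 (log2 difference 2.47, adjusted p = 0.00847), and Acta2 read 78760 ± 15100 against 47450 (0.71, adjusted p = 0.329, but 0.01 with quantile normalization, 0.0161 with median centring, 0.000813 by the mean of its probe sets and 0.00399 with the spike-in covariate). Both read near the highest value of the bladder arrays, at 60.5% of it or more, where the range of the scanner can compress differences.

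In all, 2101 of 28316 probe sets differed, 650 higher and 1451 lower in bladder (1295 of 13792 genes, 432 higher and 863 lower). Of 46 lists, 25 shifted, 8 up and 17 down. With an estimated correlation 6 kept their call, those of pancreas, cartilage and bone, skeletal muscle, intestine, adipocytes and fatty acid oxidation, and fry called 23. The estimated correlation called 0 lists without any 1 of the 6 bladder arrays, without the 2 spike-in-rich arrays or with the spike-in covariate, and 10 with quantile normalization and 9 with median centring. The reference was 1 array, without a spread of its own. The share of higher calls depended on the scaling: the median difference over all probe sets was -0.15 as deposited, 0.13 with quantile normalization (1186 higher, 1266 lower) and 0.53 with median centring (1651 higher, 859 lower). List medians below are therefore given relative to the median of all genes in the same setting. With a pseudocount of 9, 1326 probe sets differed, 566 higher and 760 lower. Leaving out single arrays gave 1409 (postnatal day 1 replicate 2) to 2620 (adult replicate 2) probe sets, with 405 and 1024 of them higher, and without the 2 spike-in-rich arrays 4087 differed, 1565 higher and 2522 lower.

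The largest excesses in bladder were Upk1b (5.96), Cnn1 (5.61), the smooth muscle calponin, and Upk3a (5.56), another uroplakin. Sptssb (5.53), a subunit of the enzyme that starts sphingolipid synthesis, Gsdmc2 (5.41), a gasdermin, Rhox5 (5.32), a homeobox gene, and Npy6r (5.18), a neuropeptide Y receptor, came next, with Snx31 (5.11), a sorting nexin, Cldn23 (5.06), a claudin, and Csrp1 (5.04), a smooth muscle LIM protein. The call of Npy6r was lost when its probe sets were averaged (2.82, adjusted p = 0.0527). The largest deficits were Kng1 (-9.43), which encodes kininogen, Ucp1 (-9.42), the uncoupling protein of brown fat, Fabp1 (-9.15), a fatty acid carrier of liver and gut, and Apoa4 (-9.10). Slc27a2 (-8.98), a fatty acid transporter, Igfbp1 (-8.97), Apoa1 (-8.95), Fgb (-8.93), a fibrinogen chain, Cyp4a14 (-8.90), and Smgc (-8.60), a salivary gland mucin, followed. Adjusted p for these 20 genes ranged from 3.18e-05 (Upk1b) to 0.0198 (Npy6r). In the bladder arrays Kng1, Ucp1, Apoa4, Fgb, Cyp4a14 and Smgc lay at or below the array median. So did Cnn1, Gsdmc2, Rhox5, Npy6r, Snx31, Cldn23 and Csrp1 in the reference. The size and order of these differences therefore depend on the pseudocount. The mean log2 value of the liver list was 8.12, 7.44 and 9.20 in postnatal day 1 replicates 1 to 3, against 14.7 in the reference.

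Of 30 contractile genes of smooth muscle, 23 were higher and 1 lower (26 and 1 when adjusted over the list alone), with a median of 2.48, adjusted p = 1.55e-23, and adjusted p = 0.0654 with an estimated correlation. Synm, an intermediate filament protein, was higher by 4.77 and Synpo2, an actin-bundling protein, by 4.36. The exception was Ldb3, which is also abundant in striated muscle (-3.13, adjusted p = 0.016), a call lost with median centring (adjusted p = 0.0567). Of 26 urothelial differentiation genes, 15 were higher and 0 lower (19 and 1 when adjusted over the list alone), with a median of 2.00, adjusted p = 1.5e-13, and adjusted p = 0.099 with an estimated correlation. Krt7, a keratin of simple and transitional epithelia, was higher by 4.06. Of 21 posterior Hox genes and bladder mesenchyme regulators, 7 were higher and 1 lower (11 and 1 when adjusted over the list alone), with a median of 1.11, adjusted p = 7.12e-05, and adjusted p = 0.0559 with an estimated correlation. Hoxa9 was higher by 3.29, Hoxd13 by 3.10 and Hoxa10 by 3.13, whereas Hoxc8, expressed further forward in the body, was lower (-3.17, adjusted p = 0.0433) and lost its call without adult replicate 1 (0.0746), adult replicate 3 (0.0586), postnatal day 1 replicate 1 (0.068) or 2 (0.0555), and in 6 other settings (adjusted p from 0.0501 to 0.102). Hoxa9 stood at 1.52 by the mean of its probe sets.

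Smaller shifts towards bladder were seen in 5 further lists. Of 15 Hedgehog pathway genes, 3 were higher and 0 lower (the same when adjusted over the list alone), with a median of 0.49, adjusted p = 0.00526, and adjusted p = 0.099 with an estimated correlation. Shh read 35020 ± 2610 (SD, n = 3) against 3351. Of 18 detrusor receptors and ion channels, 5 were higher and 0 lower (6 when adjusted over the list alone), with a median of 0.32, adjusted p = 0.00845, and adjusted p = 0.429 with an estimated correlation. Among them were Pde5a (2.98), the cyclic GMP phosphodiesterase, and P2rx1 (4.01), the ATP receptor of the detrusor. The detrusor median was 0.16 without postnatal day 1 replicate 1, 0.14 with the spike-in covariate and 0.15 with the filter at the 70th percentile, all still called, and the Hedgehog median was 0.33 with quantile normalization, also still called. Basement membrane genes (2 of 17 higher, 0 lower, 4 higher when adjusted over the list alone) had a median of 0.68, adjusted p = 0.0101, and adjusted p = 0.375 with an estimated correlation. BMP and TGF-beta pathway genes (3 of 27 higher, 1 lower, 5 and 1 when adjusted over the list alone) had a median of 0.60, adjusted p = 0.0163, and adjusted p = 0.229 with an estimated correlation. Elastic fibre genes (3 of 14 higher, 0 lower, 3 when adjusted over the list alone) had a median of 0.44, adjusted p = 0.0434, and adjusted p = 0.429 with an estimated correlation. Fbln1, fibulin, was higher by 3.27, or by 1.35 by the mean of its probe sets. The basement membrane call was lost with quantile normalization (adjusted p = 0.0668) and the filter at the 70th percentile (0.0516). The elastic fibre call was lost with quantile normalization (0.176), median centring (0.0676), that filter (0.126), without a trend (0.06), and without postnatal day 1 replicate 1 (0.0983) or 3 (0.0509). Its median was 0.28 by the mean of probe sets and 0.27 with quantile normalization.

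Markers of other organs were lower in bladder. Of 19 liver markers, 18 were lower (19 when adjusted over the list alone), with a median of -7.13, adjusted p = 2.85e-21, and adjusted p = 0.0654 with an estimated correlation. Cps1, an enzyme of the urea cycle, read 285 ± 162 (SD, n = 3) in bladder against 54660. Of 20 skin markers, 17 were lower and 1 higher (17 and 2 when adjusted over the list alone), with a median of -4.61, adjusted p = 5.97e-15, and adjusted p = 0.0546 with an estimated correlation. Krt10 was lower (-6.76) and Flg, filaggrin, too (-8.39), whereas Ivl, involucrin, was higher (3.91, adjusted p = 0.002). Of 13 pancreas markers, 11 were lower (13 when adjusted over the list alone; median -5.27, adjusted p = 5.97e-15), such as the elastase Cela2a (-6.88). Of 19 cartilage and bone markers, 14 were lower (17 when adjusted over the list alone; median -3.72, adjusted p = 7.69e-15), such as bone sialoprotein, Ibsp (-6.78). Of 13 intestine markers, 11 were lower (11 when adjusted over the list alone), with a median of -4.20 and adjusted p = 9.5e-11, such as Tff3 (-5.32), a trefoil peptide.

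Of 22 skeletal muscle markers, 14 were lower and 0 higher (16 when adjusted over the list alone), with a median of -3.44 and adjusted p = 5.41e-13. Myh4, a fast myosin, read 11.38 ± 3.76 (SD, n = 3) against 5187. Of 14 cardiac markers, 5 were lower and 1 higher (7 and 1 when adjusted over the list alone), with a median of -2.03, adjusted p = 0.00172, and adjusted p = 0.211 with an estimated correlation. Myl2, the ventricular light chain, was lower (-7.72), whereas Tnnt2, cardiac troponin T, read 48960 ± 4510 against 6850. Of 15 adipocyte markers, 8 were lower (13 when adjusted over the list alone; median -2.74, adjusted p = 4.71e-10), and of 22 fatty acid oxidation genes, 7 were lower (16 when adjusted over the list alone; median -1.27, adjusted p = 1.46e-08), such as Ehhadh (-4.95).

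Markers of 4 more tissues lost their call only with an estimated correlation. Of 8 lung markers 6 were lower (7 when adjusted over the list alone, median -3.18, adjusted p = 2.82e-07, and adjusted p = 0.0756 with an estimated correlation), such as surfactant protein C, Sftpc (-6.25). Of 20 brain markers 6 were lower (11 when adjusted over the list alone, median -1.92, adjusted p = 3.05e-07, and adjusted p = 0.099 with an estimated correlation). Of 12 kidney markers 5 were lower (9 when adjusted over the list alone, median -2.45, adjusted p = 4.19e-06, and adjusted p = 0.099 with an estimated correlation), such as Umod (-4.89), uromodulin. Of 9 erythroid markers 5 were lower (6 when adjusted over the list alone, median -2.81, adjusted p = 1.1e-05, and adjusted p = 0.0546 with an estimated correlation), such as the red cell anion exchanger Slc4a1 (-5.38), and the erythroid median was -1.64 without a filter.

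Of the lists of blood-derived cells, 4 more shifted down, with 1 to 3 members of each passing as lower, and all 4 calls were lost with an estimated correlation. Of 18 macrophage markers 2 were lower (2 when adjusted over the list alone), with a median of -1.27, adjusted p = 0.000287, and adjusted p = 0.41 with an estimated correlation. These were Csf1r (-2.62), the macrophage growth factor receptor, and Lyz2 (-2.61). Of 7 lymphocyte markers 2 were lower (3 when adjusted over the list alone), with a median of -2.01, adjusted p = 0.0163, and adjusted p = 0.271 with an estimated correlation. Of 6 MHC class II genes 1 was lower (3 when adjusted over the list alone), with a median of -1.53, adjusted p = 0.0257, and adjusted p = 0.429 with an estimated correlation. Of 8 mast cell markers 3 were lower and 1 higher (5 and 1 when adjusted over the list alone), with a median of -2.15, adjusted p = 0.0365, and adjusted p = 0.196 with an estimated correlation. Cma1, a chymase, was lower (-3.25) and Gata2, a transcription factor, higher (1.83). With quantile normalization the lymphocyte (adjusted p = 0.071), MHC class II (0.071) and mast cell (0.0523) calls were lost. The MHC class II call was also lost with a pseudocount of 165 (0.0624) and without a filter (0.0973, median -0.65), where the lymphocyte median was -0.80. The mast cell call was also lost with the filter at the 70th percentile (0.1), without the 2 spike-in-rich arrays (0.0768) and with the spike-in covariate (0.0519).

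Cell division genes did not pass as groups in the main setting between newborn bladder and whole newborns: 0 of 38 mitosis genes (median 0.37, adjusted p = 0.0736) and 0 of 33 DNA replication genes (median -0.26, adjusted p = 0.568) passed the limma test, also when adjusted over the list alone, with 3 and 0 at an unadjusted p under 0.05. The mitosis list was called, as higher, with the spike-in covariate (adjusted p = 0.00555), median centring (0.0451), a pseudocount of 165 (0.0479) or no filter (0.0215), and without postnatal day 1 replicate 1 (0.0277) or 2 (0.0169). Fibrillar collagens and their assembly (2 of 28 higher, 1 lower) had adjusted p = 0.0628, or 0.00326 with the spike-in covariate, 0.0159 with median centring, 0.0215 without a filter, 0.0187 without postnatal day 1 replicate 2 and 0.0428 without the 2 spike-in-rich arrays. Basal urothelium genes (3 of 14 higher, 1 lower, 4 and 1 when adjusted over the list alone) had adjusted p = 0.0577, or 0.039 without postnatal day 1 replicate 1, 0.0338 with the spike-in covariate and 0.0216 without a filter.

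The other lists of matrix, growth and signalling genes did not pass in the main setting. Of 11 small leucine-rich proteoglycans 1 was lower (3 lower and 1 higher when adjusted over the list alone; adjusted p = 0.565), with a median of 0.17 and a mean of -0.64. Of 18 imprinted growth genes 1 was higher (median -0.50, adjusted p = 0.259). None of 14 fetal RNA-binding and growth regulators differed (limma, 2 at an unadjusted p under 0.05; median -0.11, adjusted p = 0.826). Of 30 Wnt pathway genes 1 was higher and 1 lower (4 and 1 when adjusted over the list alone; median 0.55, adjusted p = 0.139). Of 14 retinoid pathway genes 2 were lower (2 lower and 1 higher when adjusted over the list alone; adjusted p = 0.554), with a median of 0.05 and a mean of -0.37. Of 26 immediate early genes 4 were higher and 1 lower (5 and 1 when adjusted over the list alone; median 0.27, adjusted p = 0.0756, but 0.000562 with the spike-in covariate, 0.0461 without adult replicate 2, 0.0382 without postnatal day 1 replicate 3, 0.0127 without both of these, 0.0227 without a filter and 0.0424 by the mean of probe sets). Of 18 glucocorticoid-responsive genes 2 were lower (median -0.29, adjusted p = 0.554), and none of 18 circadian genes differed (limma, 5 at an unadjusted p under 0.05; median -0.16, adjusted p = 0.826).

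None of 22 MHC class I and interferon genes differed (limma, 4 at an unadjusted p under 0.05; median -0.44, adjusted p = 0.455), and of 11 complement genes 2 were lower (2 lower and 1 higher when adjusted over the list alone; median -0.43, adjusted p = 0.351). None of 17 endothelial markers differed (limma, 0 at an unadjusted p under 0.05; median -0.37, adjusted p = 0.355). Of 11 Schwann cell markers Mal, a myelin proteolipid also made by urothelium, was higher (4.25); the list had a median of -0.58, a mean of 0.01 and a test pointing up (adjusted p = 0.835). Of 22 peripheral neuron markers 1 was higher (median 0.43, adjusted p = 0.351). Of 6 mesothelial markers 2 were higher and 1 lower (2 and 2 when adjusted over the list alone; median 0.22, adjusted p = 0.232). The higher ones were the uroplakins Upk1b (5.96), which is also a urothelial list member, and Upk3b (3.83), while Gpm6a was lower (-5.65) and Lrrn4 read -2.35 (adjusted p = 0.0812). Of 26 xenobiotic metabolism genes 4 were higher and 3 lower (6 and 6 when adjusted over the list alone; median -0.42, adjusted p = 0.542), such as Gstm1 (2.86) and the carboxylesterase Ces1d (-6.32). Of 37 oxidative phosphorylation genes 1 was higher and 2 lower (1 and 3 when adjusted over the list alone; median -0.33, adjusted p = 0.0562, but 0.00268 with quantile normalization, 0.00856 without adult replicate 2, 0.0453 without postnatal day 1 replicate 3, 0.00361 without both, 0.0345 with the spike-in covariate, 0.0322 with a pseudocount of 9 and 0.0139 with the filter at the 70th percentile). Of 33 ribosomal protein genes Rps6 was higher (1.08, adjusted p = 0.0454, or 0.48, adjusted p = 0.591, by the mean of its probe sets), and 0 were when adjusted over the list alone (median 0.06, adjusted p = 0.147, but 0.000149 with median centring, 0.000326 with the spike-in covariate, 0.0439 without postnatal day 1 replicate 2, 0.048 without a filter and 0.0188 by the mean of probe sets).

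**Figure D4:**
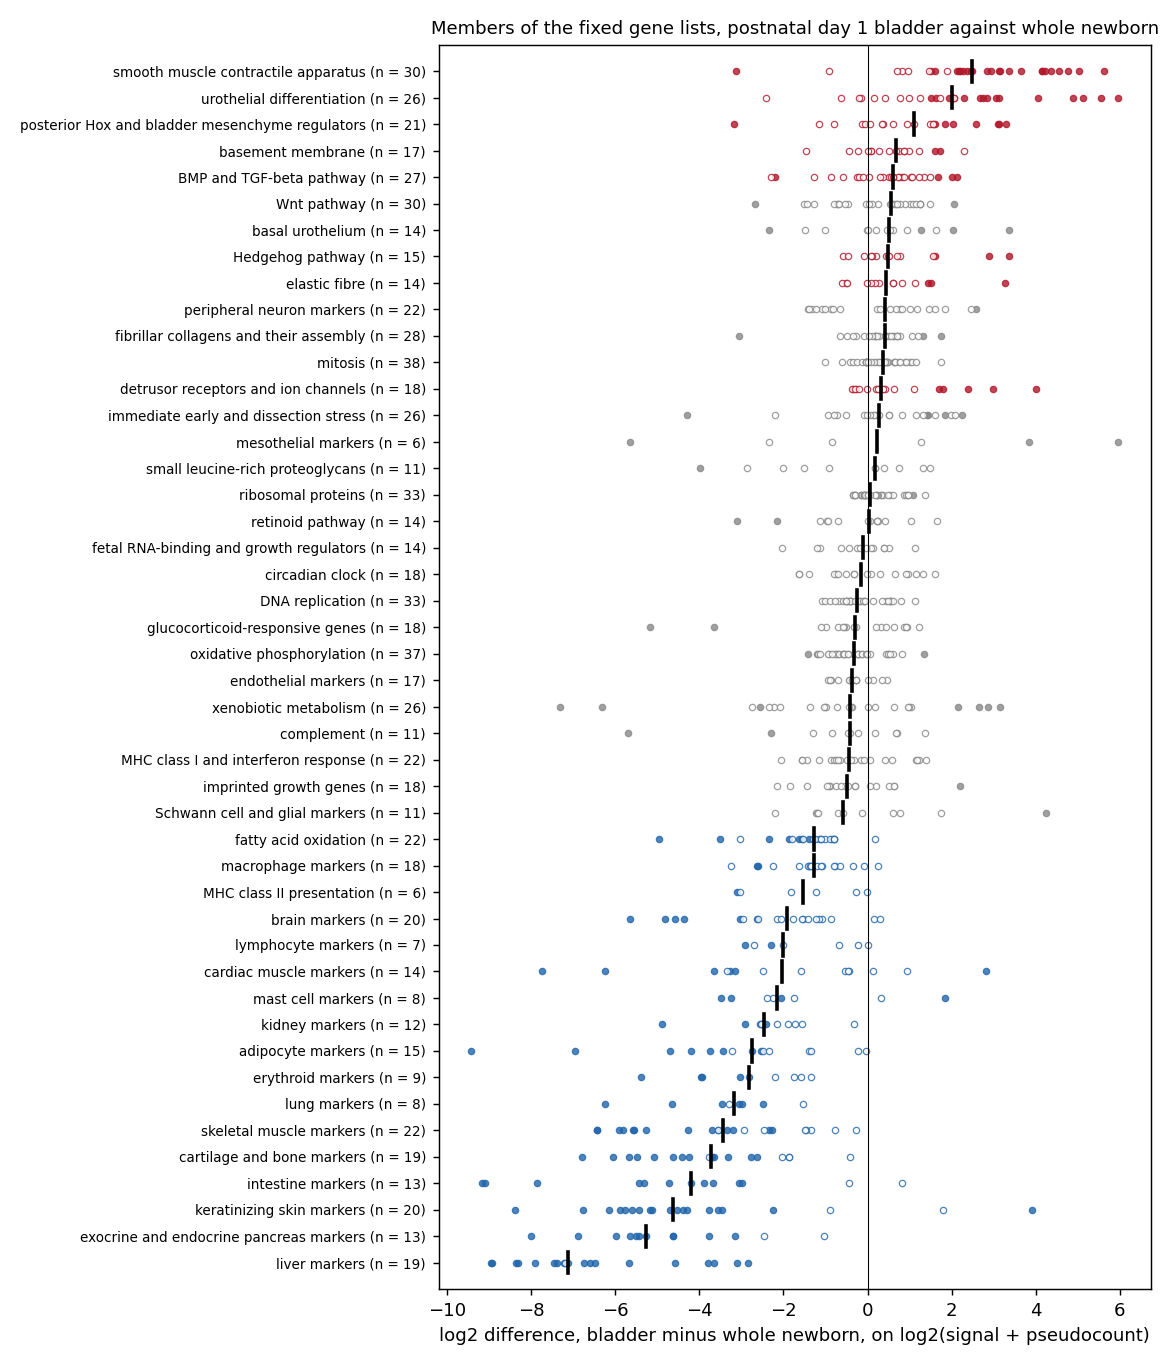
Log2 difference, postnatal day 1 bladder minus whole newborn, of each tested member of the 46 lists (1 point per gene, filled if called), with a black line at each list's median and the colours of the stage plot. Medians run from -7.13 for liver to 2.48 for smooth muscle, with the reference on 1 array.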

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

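The spike-in comparisons, the division of the striated muscle genes into a pair of parts, the cross-hybridization check, the comparison of adult replicate 2 with random lists and the accessory gland markers were chosen only after the results were seen. The hybridization spike-ins, added controls that are not bladder transcripts, read 1.154 log2 units (2.23-fold) higher in adult replicate 2 than in the other 2 adult arrays, which is what singled it out.

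In adult replicate 2, the 18 spike-in probe sets rose by nearly the same amount (SD 0.0919). Less bladder target on that array, scaled up to the common mean, would give such a rise. More of the added controls would give it too, so the small SD cannot tell these apart and less target stays undecided. Its immediate early genes stood 1.76 log2 units above the other adult arrays, at percentile 100 of 10000 random lists, but 10 of the 39 lists stood under percentile 1 (4) or over 99 (6) on this array, among them peripheral neurons (-2.24), fibrillar collagens (0.69), MHC class II (1.30), adipocytes (-0.85) and the circadian clock (-0.66), so an immediate early response stays undecided. Of 13 male accessory gland markers, 9 were lower in adult replicate 2 by over 1 log2 unit and 0 higher (median -2.77), for example Svs4 at 3149.7, 3.45 and 3861.2 in adult replicates 1 to 3, which is consistent with other tissue taken along with adult replicates 1 and 3 only. Less target and other tissue do not exclude each other, and their shares were not tested.

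The mitosis and DNA replication genes, 70 together, had a joint median of -2.97. This median was -2.98 with median centring and -3.01 with quantile normalization. The medians of the bladder arrays spanned 0.485 log2 units, and the median change of all tested probe sets was 0.02. A scaling factor moves all probe sets of an array alike. These values therefore argue against scaling of the arrays as the cause of a change of -2.97. The spike-in level, as mean log2, was 12.8, 14.1 and 13.0 in adult and 13.3, 13.0 and 13.6 in newborn bladders. The levels of the stages overlapped, and the median was -2.94 with the spike-in level as a covariate. Newborn replicate 2 and adult replicate 3 had nearly the same level. Their mean log2 values were 11.06 and 7.90 for mitosis and 11.65 and 9.77 for DNA replication. These values argue against the spike-in level as the cause of the fall, whereas other aspects of array quality stay open. Without the 2 arrays of highest spike-in signal the median was -2.10 over 46 genes, since the filter then dropped genes seen only in newborn bladder. Stage, the biological explanation, storage and the Actb ratio of 3' to 5' signal (3.84 to 5.15 in adult, 1.85 to 3.70 in newborn bladders) change together in this design and stay open, while the Gapdh ratio went the other way and overlapped (15.3 to 19.6 and 19.1 to 30.9).

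The striated muscle genes could stem from whole muscle carried with the newborn bladders, but as 1 source they should then stand at a similar share of the whole-newborn level, and their shares spanned 4.65 log2 units over 10 genes. Cross-hybridization to smooth muscle actin stays open for Acta1 (-1.78) and Actc1 (-1.90): their changes lay below that of Acta2 (difference -1.93, SE 0.383), but Acta2 read 77.1% to 96.6% of the highest value on each bladder array, where changes can be compressed. The excess over adult bladder, as a log2 ratio to the whole-newborn level, had a median of -0.37 over the 5 genes that adult bladder also shows and -3.48 over the other 5, and this difference of 3.11 (1.89 without postnatal day 1 replicate 3, and 2.19 between the median percentages, 79.1% and 17.3%) argues against muscle of the kind in whole newborns as the only source of the former set, although its Acta1 (-1.30) and Ckm (-1.69) lay near Tnnc2 (-2.30) of the latter and stay open. The division is not sharp, since Myh7 of the latter set read 331.05 in adult replicate 3, above that array's median of 234.08. Acta1 read 92727 in the reference, whose highest value was 113841, so compression can also bear on its share. Among the other 5 the range was 1.42, and Myh3 ran from 0.859% to 29% between arrays, which leaves carried muscle undecided for them. Muscle of another fibre makeup may also contribute and was not tested.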

How the results depend on the processing

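The spike-in covariate and the removal of the 2 arrays with the highest spike-in signal were chosen only after the control probe sets were seen, and the other settings before the data were examined. Of the called lists, 12 of 19 between the stages and 20 of 25 against the reference kept their call wherever tested, the estimated correlation and fry aside. Fry lost fibrillar collagens (adjusted p = 0.0511) and peripheral neurons (0.0808) among the 12. Among the 20 it lost detrusor receptors (0.0892), BMP and TGF-beta (0.0597) and macrophages (0.071). Fry also called, as lower, basal urothelium between the stages (0.0302). Against the reference it also called basal urothelium (0.0139), Wnt (0.03265) and mesothelium (0.00295) as higher and oxidative phosphorylation (0.0481) as lower. MHC class II, 1 of the 12, had too few genes for a test in 5 settings: without each adult array, without the 2 spike-in-rich arrays and with the filter at the 70th percentile. Of the called named genes, 63 of 109 and 88 of 135 kept their call wherever tested, and all 46 lost between the stages were lost without some single array. No called result changed direction; for the changes below the cause was not tested. No paired analysis was possible because the labels give no link between samples of the groups. Of the 10 splits of the 6 bladder arrays into 3 and 3, only 1, the real one, gave as many changed probe sets (1829 against at most 0) and only 1 as many shifted lists (19 against at most 16), and 10 splits cannot give a chance under 0.1. The other splits keep part of the stage difference, so their counts are no rate of false calls. Low signal limits the size of changes of genes at or below the array median, and 1 reference array limits the second comparison.

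Between the stages, 4660 probe sets changed with array weights and 3317 with the spike-in covariate, and 598 to 2219 without single arrays; 0 lists shifted with the estimated correlation. Against the reference, 1326 probe sets differed with a pseudocount of 9 and 4087 without the 2 spike-in-rich arrays, and 6 lists kept their call with the estimated correlation.

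Signs turned as follows between the stages, all without a call. With array weights: Acta2 -0.090, urothelial differentiation -0.087, retinoid pathway -0.0376, mesothelial markers -0.0719. By mean of probe sets: Acta2 -0.35, Rps9 0.13. Without the 2 arrays: Acta2 -0.0391. Urothelial differentiation read -0.0062 with quantile normalization, -0.0071 with median centring and -0.0018 with the covariate. Without a filter: retinoid pathway -0.23, mast cells 0.13, cartilage and bone -0.14. Ranges without single arrays were: Acta2 -0.16 to 0.32, Aqp3 -0.11 to 0.57, smooth muscle -0.19 to 0.034, urothelial differentiation -0.17 to 0.044, BMP and TGF-beta -0.20 to 0.050, retinoid pathway -0.098 to 0.36, mast cells -0.51 to 0.17, endothelium -0.16 to 0.31, mesothelium -0.0624 to 0.22, glucocorticoid response -0.58 to 0.042, immediate early genes -0.74 to 0.28.

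Against the reference, with values not centred on all genes, median centring turned Sox4 (0.052), Ramp2 (0.26), DNA replication (0.43), imprinted genes (0.18), fetal regulators (0.57), MHC class I (0.24), complement (0.25), endothelium (0.31), Schwann cells (0.099), oxidative phosphorylation (0.35), xenobiotic metabolism (0.26), glucocorticoid response (0.39) and circadian clock (0.52). Quantile normalization turned proteoglycans (-0.010), fetal regulators (0.021), Schwann cells (0.11) and circadian clock (0.20). By mean of probe sets: Igf1r -0.011, Tsc22d3 -0.41, proteoglycans -0.13, retinoid pathway -0.23. Without a filter: proteoglycans -0.37, retinoid pathway -0.16, mesothelium -0.69. Without the 2 arrays: retinoid pathway -0.0024, glucocorticoid response 0.045, circadian clock 0.00065. With the covariate: peripheral neurons -0.42. Ranges without single arrays: proteoglycans -0.48 to 0.28, retinoid pathway -0.0626 to 0.15, glucocorticoid response -0.51 to 0.045, circadian clock -0.44 to 0.00065.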

Other observations

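No test of this part was chosen after its result was seen; the values below belong to lists with fewer than 5 tested genes, which were not tested as groups, and the genes were picked after their values were seen. Among 4 lymphocyte markers, Il7r, the interleukin 7 receptor, was higher in adult than in newborn bladder (log2 2.07, adjusted p = 0.0117) and so was Cd52, a surface glycoprotein (2.64, adjusted p = 0.0195), whereas Ptprc, the common leukocyte antigen, did not pass the limma test (2.09, adjusted p = 0.0604), nor did Ighm, an immunoglobulin heavy chain (0.27, adjusted p = 0.677). Markers of erythroid cells (Alas2 -1.51, adjusted p = 0.15; Add2 -0.71 and Tspan33 -0.34), liver (Ttr 1.21, adjusted p = 0.154; Apoh -1.09, Rbp4 -0.61 and Apoa2 -0.56) and male accessory glands (Hoxb13 -1.13, adjusted p = 0.139; Tmprss2 0.51, adjusted p = 0.183; Svs5 1.60, adjusted p = 0.397) did not pass either. Svs5, a seminal vesicle protein, read 1312.1, 38.6 and 1279.4 in adult replicates 1 to 3. Pbsn, probasin of the prostate, read 1103.2, 54.78 and 984.29 there and 1.95 to 21.22 in newborn bladders, and was too low in 4 of the 6 bladder arrays to be tested.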
